A study of Drosophila melanogaster with 12 samples.

How the data were processed

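The deposited values came from Affymetrix arrays of whole fly heads, and each array's column was read as linear intensity. The array titles gave the replicate numbers, and for CS_50 replicate 2 the description says sample 1 instead. The authors' deposited labels name total RNA and a standard Affymetrix labelling protocol, and they state that the extraction protocol was not supplied. Neither the labels nor the deposited tables name the software that turned probe signals into probe set intensity. Each of the 12 columns had the same mean of 150.005 after trimming 2% of the values at each end, so the deposited intensity had been scaled to a common trimmed mean. The medians of the 12 arrays differed by a factor of at most 1.08, and the columns were therefore kept as deposited. Values were taken as log2(intensity + 6.26), where 6.26 was the 25th percentile of all values pooled. Of the 18952 probe sets, 183 were Affymetrix controls and were not tested. Probe sets whose mean log2 value lay at or above the 40th percentile, a signal of 11.5, were tested, which left 11261.

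Gene names came from the array annotation, matched by Entrez gene number to the genes of genome release 6. Of the tested probe sets, 9613 named exactly 1 gene, 275 named several and 1373 named none, which gave 8612 genes. Group means were fitted in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend), with all 12 arrays sharing 1 spread per probe set and 8 residual degrees of freedom. All tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 11261 tested. Standard errors are limma's moderated ones. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

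Gene lists for pathways, complexes and cell types were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 39 lists that had at least 5 tested genes. Each gene entered through its probe set of highest mean. Beside camera stood the same test with an estimated correlation, and fry, a rotation test of whether a list's genes moved on balance in 1 direction. Members were counted over all probe sets tested and again adjusted over the list alone.

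The groups, the contrasts, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule named para, List and GstS1 always. It named for each of the 4 main contrasts the 12 largest rises and the 12 largest falls among called probe sets that name 1 gene, with all 3 arrays of one group above all 3 of the other. It also named the 10 genes of lowest p in the interaction, up to 4 members of lowest p of each list that was called or had a called member, and up to 10 genes called in both lithium contrasts. List was picked by the study from these same arrays, so its values are not independent evidence.

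The alternatives were quantile normalization, no offset, double the offset, no filter on dim probe sets, a filter at the 60th percentile, no intensity trend, the 6 arrays of a contrast alone, array weights, a term for the replicate number, and each array left out in turn. A further alternative, without CS_0 replicate 3 and Shu_0 replicate 1, was chosen after seeing that these lay farthest out on the first principal component.

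The procedure was first run on simulated arrays with the fitted spread, to which known changes had been added. Of 80 added changes of log2 0.5, it called 23 in the interaction and 44 to 57 in the 4 main contrasts. Of 80 added changes of log2 1, it called between 53 in the interaction and 73 in the mutant against the wild type on lithium. Of 40 added changes of log2 2, it called 39 or 40 in each contrast.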

Results

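RNA from whole heads of Drosophila melanogaster was measured on 12 Affymetrix arrays, which fall into 4 groups of 3. CS_0 is the wild type without treatment, CS_50 the wild type on 50 mM lithium, Shu_0 the mutant Shu without treatment, and Shu_50 the mutant on 50 mM. The gene annotation lists Shu, or Shudderer, as a name of para, the gene of the fly's voltage-gated sodium channel (X:16455027-16533096, genome release 6). For Shu_50 the labels give the dose without naming the drug, and the title of the series names lithium. Sex, age and length of treatment were not given, and nothing says whether the 3 replicates of a group came from separate cultures. Array medians lay between 23.9 and 25.8 intensity units, replicates of a group correlated at 0.985 to 0.989, and the number of arrays limits the precision. On the first principal component, which held 18.1% of the variance, CS_0 replicate 3 (-20.5) and Shu_0 replicate 1 (17.9) lay farthest out. In each comparison 11261 probe sets were tested, and chance gives about 563 with an unadjusted p under 0.05. The arrays of the groups compared did not overlap, in either direction, for 2156 (lithium, wild type), 1776 (lithium, mutant), 2611 (genotypes untreated) and 2132 probe sets (genotypes on lithium). Errors after ± are SE with n = 3 arrays per group unless stated, and all p values are adjusted as described under the processing.

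Lithium in the wild type (CS_50 against CS_0) asked what the drug changed in heads without the mutation. The largest rises among the genes named by the rule were those of a UDP-glycosyltransferase and an amino acid transporter. Ugt37A3 (probe set 1638182_at, 3R:12741958-12743680), the glycosyltransferase, rose 11.3-fold from a mean signal of 91.6 to 1304 (log2 3.50 ± 0.43, adjusted p = 0.000222), with an SD of 909 between the 3 lithium arrays. List (1636594_at, 2R:18727817-18730281), an amino acid transporter of the SLC6 family, rose 5.62-fold from 111 to 651 (log2 2.49 ± 0.09, adjusted p = 2.69e-11). A further probe set of List gave log2 2.45 ± 0.12. Probe set 1626311_at of List was dim, with a mean signal of 22.4 in CS_0, and its log2 difference of 0.15 ± 0.29 was not called and turned to -0.18 without CS_0 replicate 2. The study picked List from these arrays, so its rise is not independent evidence.

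Further large rises were those of the cytochrome P450 Cyp309a1 (log2 1.72 ± 0.17, adjusted p = 2.42e-05), CG15784 (1.69), CG7763 (1.31), CG11425 (1.15), the aldehyde oxidase AOX1 (1.31 ± 0.20, adjusted p = 0.00191) and the glutathione transferase GstD2 (1.10 ± 0.18, adjusted p = 0.00382). The calls of AOX1 and GstD2 were lost without the intensity trend (adjusted p = 0.0610 each). Arc1, an activity-regulated gene whose protein forms capsids, rose by 1.19 ± 0.12 (probe set 1639180_at, adjusted p = 5.30e-05) and by 1.08 from probe set 1639694_s_at. Nmdmc, a mitochondrial enzyme of folate metabolism, rose by 1.47 ± 0.17 (adjusted p = 0.000153), and Bcat, which transfers the amino group of branched-chain amino acids, by 1.12 ± 0.13 (adjusted p = 0.000121). Among the lower genes were the non-coding lncRNA:CR31781 (-1.46 ± 0.17, adjusted p = 0.000155), wrapper, an adhesion protein of midline glia (-0.85 ± 0.10, adjusted p = 0.000222), CG5653 (-0.73) and CG16756 (-0.56). Transferrin 1 (Tsf1), an iron-binding protein of the hemolymph, fell by 0.54 ± 0.10 (adjusted p = 0.00783), a call lost without CS_50 replicate 3 (adjusted p = 0.0670). CG9377 fell by 1.93 ± 0.39 (adjusted p = 0.0157), also lost without that array (adjusted p = 0.0971).

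Of the 38 genes of amino acid metabolism, 7 rose and none fell (16 and 4 at an unadjusted p under 0.05 by limma), and 14 were higher and 3 lower when adjusted over the list alone. Those that rose included Ahcy, which clears S-adenosylhomocysteine (1.00 ± 0.09, adjusted p = 1.66e-05), Shmt, which passes a one-carbon unit from serine to folate (0.60 ± 0.07, adjusted p = 0.000222), the phosphoserine phosphatase aay (0.48 ± 0.05, adjusted p = 0.000105), the glycine decarboxylase CG3999 (0.76), CG8745 (0.78) and CG11899 (0.31), whose call was lost without CS_50 replicate 2 (adjusted p = 0.101). The list's median was 0.0828 and its mean 0.154, with adjusted p = 0.000484 at the preset correlation, adjusted p = 0.435 with an estimated correlation and adjusted p = 0.00277 by fry. Among 16 tRNA synthetases 2 rose, CysRS (0.53) and TyrRS (0.34), and both calls were lost without CS_50 replicate 3 (adjusted p = 0.137 and 0.164). The list had adjusted p = 0.0207, and adjusted p = 0.513 with an estimated correlation. None of the 28 proteasome genes was called by limma, 11 were higher and none lower at an unadjusted p under 0.05, and their median of 0.116 had adjusted p = 6.59e-06, or adjusted p = 0.513 with an estimated correlation. Of 30 glutathione transferases 3 rose, GstD2, GstE7 (0.64) and GstE9 (0.32), and the list was not called (adjusted p = 0.0859). Without CS_50 replicate 3 neither GstE7 (adjusted p = 0.0820) nor GstE9 (adjusted p = 0.137) was called.

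Other lists lay lower. Of 16 antimicrobial peptide genes, 2 fell, Drsl4 (-0.43) and BomS2 (-0.35), and 6 were lower and 1 higher when adjusted over the list alone (median -0.191, adjusted p = 0.000739, adjusted p = 0.513 with an estimated correlation). BomS2 was not called without CS_50 replicate 3 (adjusted p = 0.104). Of 20 fat body markers 2 fell, Tsf1 and apolpp, the lipophorin precursor (-0.41), and 7 were lower when adjusted over the list alone (median -0.0955, adjusted p = 0.0176, adjusted p = 0.513 with an estimated correlation). The call of apolpp was lost without CS_50 replicate 3 (adjusted p = 0.137). Of the 63 genes of oxidative phosphorylation 2 fell, with a median of -0.0592 (adjusted p = 7.12e-05, adjusted p = 0.525 with an estimated correlation). For 31 ribosomal protein genes the median was -0.148 (adjusted p = 1.25e-06, adjusted p = 0.525 with an estimated correlation), and it turned to 0.0429 under quantile normalization, so no direction is given. Photoreceptor, synaptic, neuropeptide and female-enriched lists were also called lower at the preset correlation, with adjusted p values from 0.00747 to 0.0207, and for the 11 called lists the adjusted p with an estimated correlation lay between 0.435 and 0.525, so none was called with it. The means of glial (-0.0568, SE 0.0229) and male-enriched markers (-0.294, SE 0.135) were also lower without overlap of the arrays, and these lists were not called (adjusted p = 0.229 and 0.294). By fry amino acid metabolism was the 1 list called. As a sign of RNA quality beside these lists, the log2 ratio of 3' to 5' signal was taken for control genes. For eIF-4a this log2 ratio was 2.77 in CS_0 and 2.48 in CS_50. For GAPDH it was 1.03 and 0.947, with no overlap of the arrays in either gene. For actin, the remaining control gene, it was 1.22 and 1.13, and the arrays overlapped. Whether RNA quality bears on these lists was not tested.

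In all, 182 probe sets were called, 112 higher and 70 lower, for 145 named genes, and 22 changed more than 2-fold. Of 19 called genes with several tested probe sets, 5 had probe sets of opposite sign and 17 had one that was not called. At an unadjusted p under 0.05 there were 1479. The count was 118 without the filter on dim probe sets, 44 without the intensity trend, and 94, 112, 84 and 78 without CS_0 replicate 3, CS_0 replicate 1, CS_50 replicate 2 and CS_50 replicate 3 in turn. Of the 27 genes named here by the rule, 17 were called under every alternative and 7 lost the call without some single array.

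**Figure D1:**
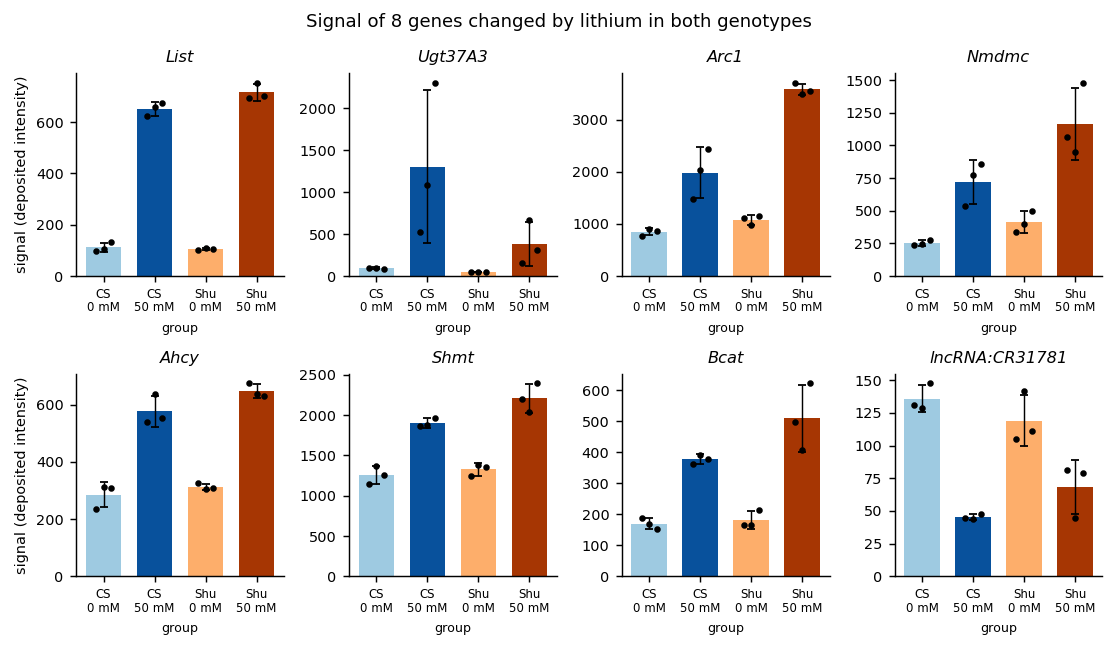
Mean intensity (bars, error bars SD, dots the 3 arrays) of 8 genes in the 4 groups. List rose from 111 to 651 in the wild type and from 104 to 715 in the mutant, and lncRNA:CR31781 fell in both.

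Lithium in the mutant (Shu_50 against Shu_0) asked what the drug changed in Shu heads. List rose again, 6.52-fold from 104 to 715 (log2 2.70 ± 0.09, adjusted p = 7.19e-12), and Ugt37A3 5.74-fold (2.52 ± 0.43, adjusted p = 0.00317), though not called without the intensity trend (adjusted p = 0.0718). Arc1 (2R:14357927-14360297) rose by 2.15 ± 0.16 from probe set 1639694_s_at (adjusted p = 5.81e-07) and by 1.73 ± 0.12 from 1639180_at. Amino acid metabolism was the list with the most called members, 12 of 38 genes, all higher. The metal-binding MtnD rose by 1.57 ± 0.30 (adjusted p = 0.0079), a call lost without Shu_0 replicate 1 (adjusted p = 0.0608).

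Further rises were those of CG7763 (1.53), Nmdmc (1.48 ± 0.17, adjusted p = 9.8e-05), Bcat (1.45 ± 0.13, adjusted p = 5.66e-06), Cyp309a1 (1.11, adjusted p = 0.00106), CG15784 (1.11), CG11425 (1.11) and the cuticle gene Cpr64Ac (0.97, adjusted p = 0.00131). Among the lower genes, dhd, a thioredoxin of the female germline, fell from a mean signal of 49.1 to 6.85 (adjusted p = 0.0197). Its log2 size of -1.96 depends on the offset (-1.57 with double the offset). The call was lost without Shu_0 replicate 2 (adjusted p = 0.101), the array where dhd was highest (80.4). The mean over ovary and chorion markers was 1.35 in that array, beside -0.0909 and -0.408 in Shu_0 replicates 1 and 3. In the wild type, CS_0 replicate 2 had the highest marker mean (1.59) and the highest dhd signal (42.8, beside 11.6 and 7.31). Shu_0 replicate 3 went the other way, with a dhd signal of 43.4 at the lowest marker mean of its group. Whether the ovary and chorion markers bear on the fall of dhd was not tested. Further falls were those of CG7227 (-1.21, adjusted p = 0.000382), CG5653 (-1.12 ± 0.11, adjusted p = 1.38e-05), the cuticle gene Acp65Aa (-0.96 ± 0.11, adjusted p = 7.01e-05), the neprilysin-like Nepl6 (-0.72, adjusted p = 0.00363) and the carbonic anhydrase CAH9 (-0.65, adjusted p = 0.00124). The fall of lncRNA:CR31781 (-0.78, adjusted p = 0.0213) was not called without Shu_0 replicate 2 (adjusted p = 0.0973), nor that of Tsf1 probe set 1639442_a_at (-0.77, adjusted p = 0.0168) without Shu_0 replicate 1 (adjusted p = 0.113). Tsf1 probe set 1632430_at, the one given for the wild type, fell by 0.54 in the mutant as well (adjusted p = 0.00580) and was called without any 1 array.

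The 12 genes of amino acid metabolism that rose included the serine and glycine enzymes CG11899 (0.55 ± 0.07, adjusted p = 0.000122), aay (0.52 ± 0.05, adjusted p = 2.66e-05), Shmt (0.73 ± 0.07, adjusted p = 1.93e-05) and CG3999 (0.78). Ahcy rose by 1.03 ± 0.09 (adjusted p = 6.56e-06) and CG8745 by 0.83 ± 0.07 (adjusted p = 1.87e-06). Adjusted over the list alone, 15 were higher and 1 lower, with a median of 0.142 and a mean of 0.219. This was the one list that held under each test, with adjusted p = 1.95e-10 at the preset correlation, adjusted p = 0.0249 with an estimated correlation and adjusted p = 0.000103 by fry. Of 27 genes of carbohydrate metabolism 5 rose, among them the maltase Mal-B2 (0.64), the gluconeogenic fbp (0.40) and Pepck2 (0.85), and Pgi (0.33). The list had a median of 0.0236 (adjusted p = 0.0354, adjusted p = 0.664 with an estimated correlation), and 6 were higher and 1 lower when adjusted over the list alone.

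Of 16 activity-regulated genes Arc1 alone rose, and 3 were higher when adjusted over the list alone (median 0.0733, adjusted p = 0.0354, adjusted p = 0.625 with an estimated correlation and 0.0476 by fry). No gene of oxidative phosphorylation was called by limma, 13 were lower and none higher at an unadjusted p under 0.05, and their median was -0.0975 (adjusted p = 4.26e-07, adjusted p = 0.664 with an estimated correlation). Among the antimicrobial genes Drsl4 fell (-0.49, list median -0.179, adjusted p = 0.0354, adjusted p = 0.664 with an estimated correlation), and among the neuropeptides the insulin-like Ilp5 (-0.29, list median -0.0756, adjusted p = 0.0231, adjusted p = 0.288 with an estimated correlation and 0.0221 by fry). The call of Ilp5 was lost without Shu_50 replicate 1 (adjusted p = 0.0597). Proteasome genes had a median of 0.0673, with none called by limma and 5 higher at an unadjusted p under 0.05 (adjusted p = 0.00776, adjusted p = 0.664 with an estimated correlation). Among muscle genes Act87E rose by 0.50 and TpnC41C by 0.44, and the list was not called (adjusted p = 0.0760). The mean over the muscle markers was higher by 0.0791 (SE 0.0340), without overlap of the arrays.

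In the mutant 209 probe sets were called, 136 higher and 73 lower, for 173 named genes, and 22 changed more than 2-fold. Of 18 called genes with several tested probe sets, 4 had probe sets of opposite sign and 15 had one that was not called. At an unadjusted p under 0.05 there were 1340. The count was 91 without the intensity trend and 127 without Shu_0 replicate 1. Of the 27 genes named by the rule, 18 were called under every alternative and 7 lost the call without some single array.

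Whether the genotypes responded alike was compared through the probe sets called in both, since the 2 lithium contrasts share no array. Of these, 69 were higher in both, where 1.35 are given by independent lists, and 29 were lower in both, where 0.454 are. In opposite directions there was 1, a probe set that names no gene. Across the 11261 probe sets, which are not independent replicates, the changes correlated at 0.273 (jackknife SE 0.0448), and the value was 0.103 without the filter on dim probe sets and 0.507 with a filter at the 60th percentile. Called in both were the purine synthesis genes Gart (0.62 in the wild type and 0.83 in the mutant) and Pfas (0.47 and 0.70), and the folate enzyme pug (0.29 and 0.59), whose call in the wild type was lost without CS_0 replicate 2 (adjusted p = 0.111). So were Tdh (0.59 and 0.75), the ketone body enzyme SCOT (0.63 and 0.78), the aldolase Ald1 (0.40 and 0.50), the transaldolase Taldo (0.41 and 0.46), smp-30 (0.64 and 0.77) and the tetraspanin Tsp42Ed (0.80 and 0.62).

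**Figure D2:**
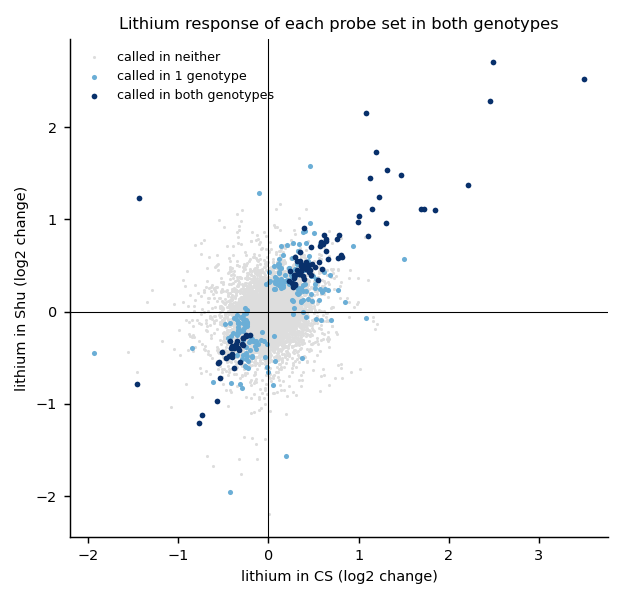
Each point is a probe set, with its log2 change on lithium in the wild type on the horizontal axis and in the mutant on the vertical axis. The 69 probe sets called higher in both and the 29 called lower in both lie along the rising diagonal.

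The mutant against the wild type without lithium (Shu_0 against CS_0) asked what the mutation's stock differs in at rest. Among the genes named by the rule, DptB (1638235_at, 2R:18867391-18867895), an antimicrobial peptide of the diptericin family, stood highest. It was 11.7-fold higher, at a mean signal of 2766 (SD 1685) against 297 (SD 320; log2 3.54 ± 0.70, adjusted p = 0.0103), and without CS_0 replicate 1 the log2 difference was 4.38 (adjusted p = 0.00329). Also higher were the attacin AttD (adjusted p = 0.0136), from a mean signal of 2.03 to 23.5, so that its log2 size of 1.73 depends on the offset (1.23 with double the offset), the cecropin CecB by 1.45 ± 0.34 (adjusted p = 0.0242) and PGRP-SB1, an amidase that cleaves bacterial peptidoglycan, by 1.45 ± 0.31 (adjusted p = 0.0149). All 4 calls were lost without Shu_0 replicate 1 alone, where DptB had 3.08 (adjusted p = 0.0672), AttD 1.38 (adjusted p = 0.0861), CecB 1.24 (adjusted p = 0.125) and PGRP-SB1 1.20 (adjusted p = 0.0896). Replicate 1 was the array of highest DptB in the other groups as well (667 in CS_0, 563 in CS_50 and 1137 in Shu_50), and likewise for PGRP-SB1. The reason for this was not tested.

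Of the genes named by the rule for the largest rises and falls, those called under every alternative were CG31809 (1641412_at, 2L:16853620-16858714), which was 5.42-fold higher (26.3 against 169.7 in the mutant, log2 2.44 ± 0.15, adjusted p = 1.09e-07), and CanA-14F, a catalytic subunit of calcineurin (1.02 ± 0.15, adjusted p = 0.00224). On the lower side those were hgo (2L:11136393-11138565), which opens the ring of homogentisate in tyrosine breakdown (-0.86 ± 0.09, adjusted p = 5.34e-05), CG7299 (-0.84 ± 0.07, adjusted p = 1.42e-05), CG17364 (-0.85, adjusted p = 0.000928) and Dyro (-0.87, adjusted p = 0.00277). Lower as well were CG9377 (69.7 against 7.22 in the mutant, adjusted p = 0.00194), whose log2 size of -2.64 depends on the offset (-2.12 with double the offset), and the cytochrome P450 Cyp6a2 (-0.84, adjusted p = 0.00453), neither called without CS_0 replicate 3 and Shu_0 replicate 1 together (adjusted p = 0.0619 and 0.112). Further called genes were Fbp2 (1.07 ± 0.26, adjusted p = 0.0247), lost without CS_0 replicate 2 (adjusted p = 0.0829), and the chloride channel ClC-a (-1.17, adjusted p = 0.0376), lost without CS_0 replicate 3 (adjusted p = 0.182). The odorant receptor Or35a (-1.25, adjusted p = 0.0408) was lost without that array too (adjusted p = 0.152), and the receptor kinase Nrk (-1.36, adjusted p = 0.0387) without Shu_0 replicate 1 (adjusted p = 0.144). In Shu_0 the mean signals of ClC-a (5.83), Or35a (5.25) and Nrk (4.58) lay below the offset of 6.26, so these log2 sizes depend on it, and with double the offset they were -0.87, -0.89 and -0.96. For para itself the mean signal was 89.9 against 73.5, with all 3 mutant arrays above all 3 wild type arrays, and its log2 difference of 0.27 ± 0.10 was not called (adjusted p = 0.156). Such separation, in one direction or the other, held for 2611 of the 11261 probe sets here. GstS1, the remaining gene named in advance, was not called in any of the 4 comparisons.

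Among 31 synaptic vesicle and transmitter synthesis genes 8 were lower, with 13 lower and 1 higher when adjusted over the list alone (median -0.116, adjusted p = 0.000175, adjusted p = 0.58 with an estimated correlation). They included the vesicular acetylcholine transporter VAChT (-0.33), complexin (cpx, -0.72), Amph (-0.26) and Rab3 (-0.28). Each of these calls was lost when some single array was left out. Without Shu_0 replicate 1 VAChT stood at -0.28 (adjusted p = 0.0534) and Rab3 at -0.26 (adjusted p = 0.0816), and without CS_0 replicate 3 cpx at -0.60 (adjusted p = 0.0636) and Amph at -0.21 (adjusted p = 0.0767). Of 63 oxidative phosphorylation genes 4 were higher, with 9 higher when adjusted over the list alone (median 0.105, adjusted p = 8.99e-05, adjusted p = 0.597 with an estimated correlation). The complex I subunit ND-B18 was higher by 0.35, and COX4 by 0.23, a call lost without CS_0 replicate 3 (adjusted p = 0.148). Of 69 mitochondrial ribosomal protein genes mRpS7 was higher (0.29), with a list median of 0.0939 (adjusted p = 0.00368, adjusted p = 0.58 with an estimated correlation). The mean over fat body markers was higher by 0.164 (SE 0.0519) beside these. Those over pan-neuronal (-0.144, SE 0.0521) and glial markers (-0.0434, SE 0.0219) were lower, with no overlap of the arrays in any of them. The log2 ratio of 3' to 5' signal of eIF-4a was 2.77 in CS_0 and 2.54 in Shu_0, also without overlap, while those of actin and GAPDH overlapped. Of 13 pan-neuronal markers 2 were lower, the transcription factor onecut (-0.66) and Cadps (-0.70), and the list was not called (adjusted p = 0.124). Cadps was not called without Shu_0 replicate 1 (adjusted p = 0.0782).

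Of 16 antimicrobial genes 3 were higher and 1 lower, with 5 higher and 3 lower when adjusted over the list alone. The list's median of -0.00205 and its mean of 0.525 differed in sign, and it was not called (adjusted p = 0.818). Among 52 cuticle genes 4 were higher, including Acp65Aa (0.87, adjusted p = 0.000439) and Cpr62Bc (0.50), and the list was not called (adjusted p = 0.297). Further called genes were the clock genes Pdp1 (-0.33) and cwo (-0.43), the potassium channel SK (-0.54), the sodium pump subunit nrv2 (-0.52) and, among activity-regulated genes, kay (-0.61). The call of cwo was lost without Shu_0 replicate 1 (adjusted p = 0.0596).

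Without lithium 571 probe sets were called, 238 higher and 333 lower in the mutant, for 480 named genes, and 26 differed more than 2-fold. Of 106 called genes with several tested probe sets, 51 had probe sets of opposite sign and 97 had one that was not called. At an unadjusted p under 0.05 there were 2252. The count was 155 without CS_0 replicate 3, 129 without Shu_0 replicate 1, 261 without Shu_0 replicate 3 and 31 without the first 2 of these together, where the 8 other pairs of 1 array from each group left 80 to 564. It was 324 with the 6 arrays alone and 59 without the intensity trend. Of the 24 genes named by the rule, 6 were called under every alternative and 14 lost the call without some single array.

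**Figure D3:**
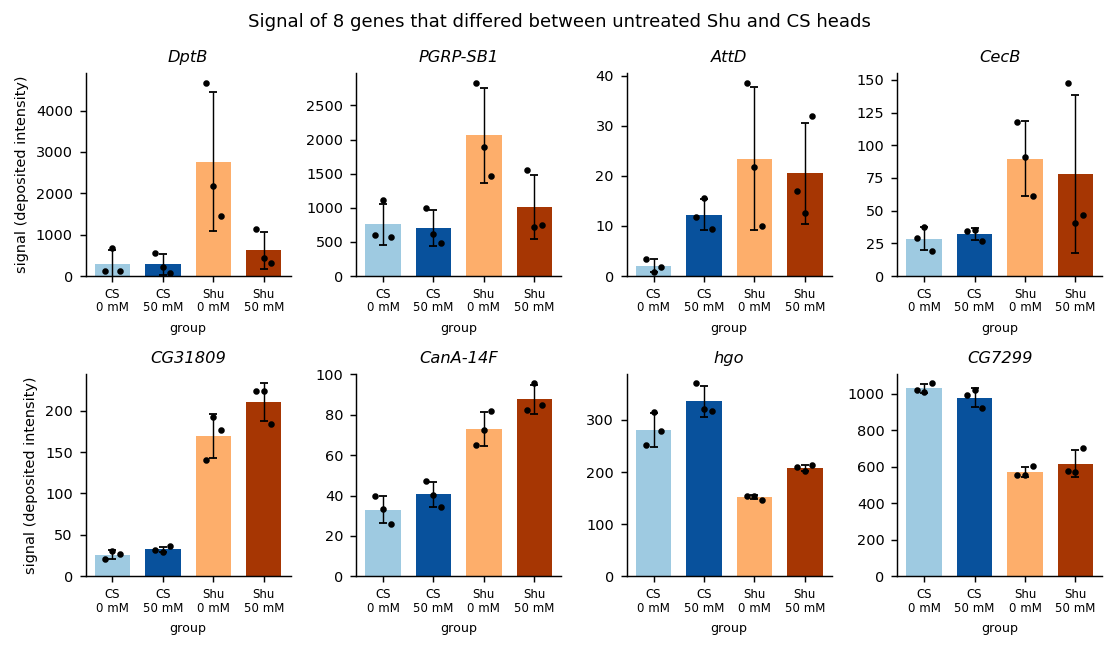
Mean intensity (bars, error bars SD, dots the 3 arrays) of 8 genes that differed between genotypes. CG31809 stood at 26.3 in CS_0 and 169.7 in Shu_0, and DptB had SDs of 320 and 1685 around means of 297 and 2766.

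The same comparison on lithium (Shu_50 against CS_50) asked what differs between the stocks while both take the drug. CG31809 was again higher, by 2.47 ± 0.15 (adjusted p = 8.94e-08), and CanA-14F by 1.01 (adjusted p = 0.0032). Arc1 was higher by 1.09 ± 0.16 (adjusted p = 0.00164), a call lost without the intensity trend (adjusted p = 0.0709). On the lower side, hgo differed by -0.67 ± 0.09 (adjusted p = 0.000675), CG7299 by -0.66 (adjusted p = 0.000247) and the odorant binding protein Obp99a by -0.64 (adjusted p = 0.000675). Had1 was higher by 0.70 (adjusted p = 0.000675), CG14630 by 0.79, CG5172 by 0.69 and CG8112 by 0.63. The genes CanA-14F (X:16560684-16587172) and Had1 (X:16306912-16308667) lie near para, the mutated locus.

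Other called genes were lost without some single array, and some under most of the 22 alternatives (pyd under 17, Est-Q 15, RSG7 14). They included the channel gene Cngl (0.97, adjusted p = 0.0849 without Shu_50 replicate 1), lncRNA:CR32368 (1.10, adjusted p = 0.0722 without Shu_50 replicate 1), yellow-d2 (0.71, adjusted p = 0.0784 without Shu_50 replicate 2) and CG4269 (1.15, or 0.92 with double the offset since its mean signal in CS_50 was 11.01, adjusted p = 0.131 without CS_50 replicate 3). Among the lower genes they included RSG7 (-0.69, adjusted p = 0.215 without CS_50 replicate 3), the carnitine acyltransferase CROT (-0.49, adjusted p = 0.130 without Shu_50 replicate 2), the esterase Est-Q (-0.47, adjusted p = 0.190 without Shu_50 replicate 2), the junction protein pyd (-0.39, adjusted p = 0.204 without Shu_50 replicate 1) and CG17364 (-0.69, adjusted p = 0.0570 without Shu_50 replicate 1).

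Probe sets called in both genotype comparisons, which share no array, were 26 higher in both (0.782 given by independent lists) and 13 lower in both (0.591). In opposite directions there was 1, CG8323, at 0.38 without and -0.48 on lithium. Each of its calls was lost under 9 of 22 alternatives, with adjusted p = 0.106 untreated without CS_0 replicate 2 and adjusted p = 0.129 on lithium without CS_50 replicate 1. Besides the genes above, SCOT was higher in both (0.47 and 0.62), as were the chitin deacetylase serp (0.34 and 0.39) and CG13043 (0.75 and 0.41), and Rab3-GEF, an exchange factor of the vesicle protein Rab3, was lower in both (-0.50 and -0.32). On lithium, Rab3-GEF was not called without CS_50 replicate 3 (adjusted p = 0.0797), nor CG13043 (adjusted p = 0.110). For para the difference was 0.34 ± 0.10 (adjusted p = 0.181), and averaged over both treatments 0.31 ± 0.07 (adjusted p = 0.0175), a call lost without CS_0 replicate 3 and Shu_0 replicate 1 together.

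Of the gene lists, oxidative phosphorylation was higher on lithium as well, with ND-B18 called (0.27, adjusted p = 0.152 without CS_50 replicate 2) and a median of 0.0818 (adjusted p = 2e-05, adjusted p = 0.515 with an estimated correlation). None of 20 fat body markers was called by limma (8 were higher at an unadjusted p under 0.05), with 5 higher when adjusted over the list alone (median 0.0951, adjusted p = 0.00321, adjusted p = 0.512 with an estimated correlation). In amino acid metabolism hgo was lower, while 5 were higher and 1 lower when adjusted over the list alone (median 0.0585, adjusted p = 0.0284, adjusted p = 0.515 with an estimated correlation). Ribosomal protein genes had a median of 0.117 (adjusted p = 0.000699, adjusted p = 0.642 with an estimated correlation) that turned to -0.0219 under quantile normalization. For the 11 lists called at the preset correlation the adjusted p with an estimated correlation lay between 0.512 and 0.642, so none held. The synaptic list was among them (median -0.0614, adjusted p = 0.0446). Beside these lists, the means over fat body (0.202, SE 0.0271), muscle (0.0770, SE 0.0371) and male-enriched markers (0.386, SE 0.168) were higher in the mutant without overlap of the arrays.

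On lithium 57 probe sets were called, 37 higher and 20 lower in the mutant, for 46 named genes, and 7 differed more than 2-fold. Of 7 called genes with several tested probe sets, 4 had probe sets of opposite sign and 5 had one that was not called. At an unadjusted p under 0.05 there were 1307. The count was 25 without the intensity trend, 133 with array weights, 100 with a term for the replicate number, and 30 without CS_50 replicate 3 and again without Shu_50 replicate 1. Of the 24 genes named by the rule, 9 were called under every alternative and 14 lost the call without some single array.

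**Figure D4:**
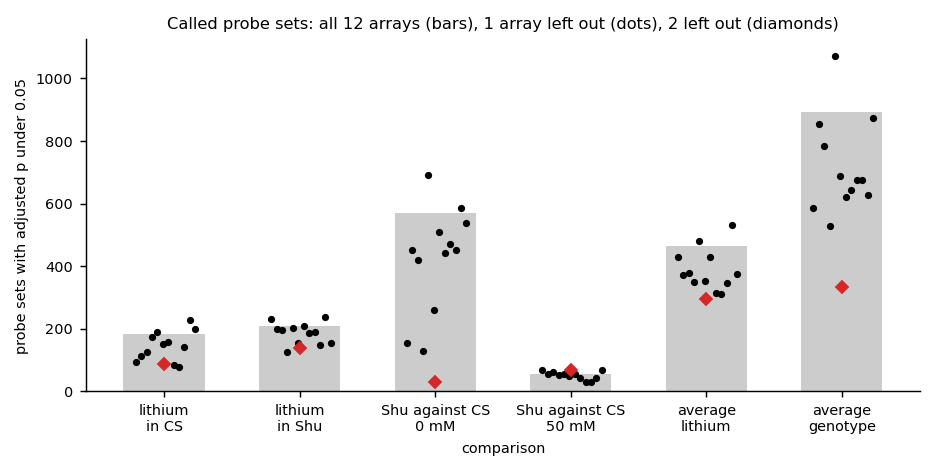
Number of called probe sets in each comparison with all 12 arrays (bars), with 1 array left out (dots) and without CS_0 replicate 3 and Shu_0 replicate 1 (diamonds). The bar for the untreated genotypes stands at 571 and its diamond at 31.

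The interaction asked whether lithium acted differently in the mutant, or equally whether the genotype difference changed on lithium. By limma 1 probe set was called, 1634590_at, which names no gene, and 758 had an unadjusted p under 0.05, more than the 563 given by chance. It was chosen for mention after its values were seen. It fell on lithium in the wild type (log2 -1.43) and rose in the mutant (1.23), a gap of 2.66 between opposite changes (adjusted p = 0.0416) whose size depends on the offset, and the signals were 43.0, 45.0 and 18.3 in CS_0, 9.10, 8.39 and 7.78 in CS_50, 11.2, 6.77 and 8.23 in Shu_0, and 27.5, 33.7 and 25.1 in Shu_50. No named gene passed. The nearest were CG8323 (-0.87 ± 0.14, adjusted p = 0.0613), the actin Act87E (0.44, adjusted p = 0.154), CG8112 (0.52, adjusted p = 0.197) and Arc1 (probe set 1639694_s_at, 1.07 ± 0.22, adjusted p = 0.389), then CAH9 (-0.65, adjusted p = 0.428) and the lipid droplet protein Jabba (-0.60, adjusted p = 0.563). So the larger count of genotype differences without lithium, and the larger rise of Arc1 in the mutant, were not shown gene by gene to depend on the other factor. The count was 2 under quantile normalization, with array weights and with a term for the replicate number, 0 without the filter, with a filter at the 60th percentile and without the intensity trend, and 0 without CS_0 replicate 1, without any 1 of the 3 Shu_0 arrays, without CS_50 replicate 2 and without any 1 of the 3 Shu_50 arrays.

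Averaged over genotypes, lithium changed 465 probe sets, 269 higher and 196 lower, for 396 named genes. Averaged over treatments, 892 differed between genotypes, 383 higher and 509 lower in the mutant, for 745 named genes. Without the intensity trend these counts were 223 and 329, and without CS_0 replicate 3 and Shu_0 replicate 1 together 295 and 333. Without Shu_0 replicate 1 alone the genotype count was 528, and without CS_0 replicate 3 alone 587.

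**Figure D5:**
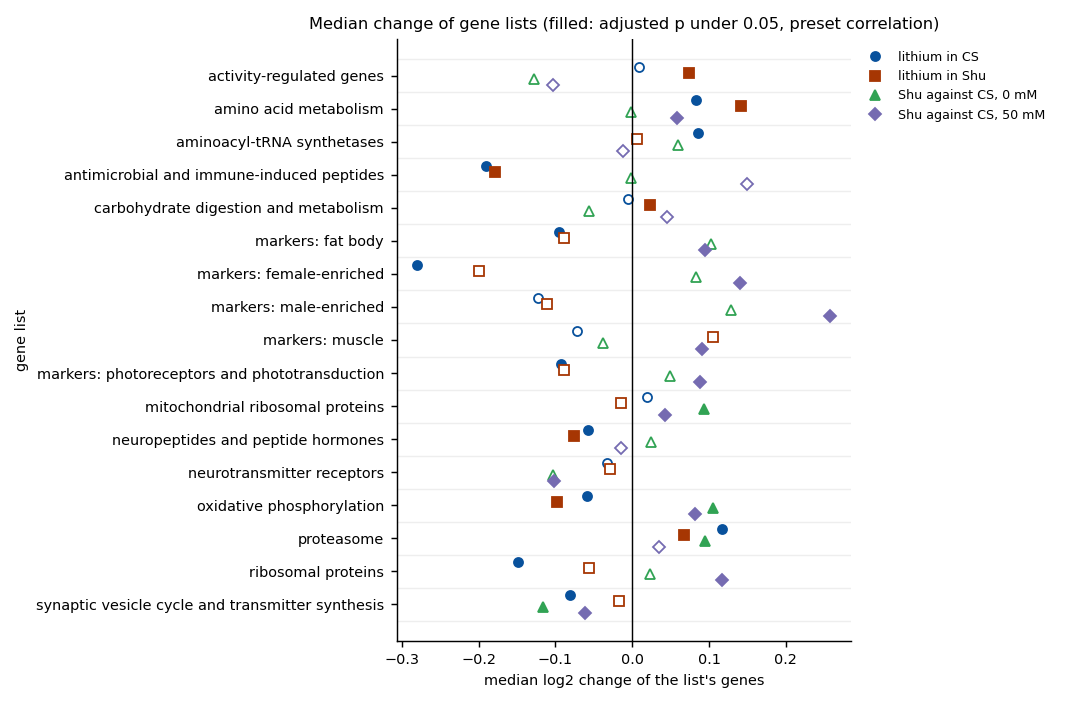
Median log2 change of the genes of each list in the 4 comparisons, filled where the adjusted p at the preset correlation was under 0.05. Amino acid metabolism stood at 0.0828 and 0.142 on lithium, and ribosomal protein medians change sign under quantile normalization (0.0429 and -0.0219 in the wild type on lithium and in the genotypes on lithium).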

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

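Of the tests in this part, the one on marker lists of other cell types, the splits for the interaction and the count without CS_0 replicate 3 and Shu_0 replicate 1 were chosen only after the result was seen. The conditions for reading the tests of single arrays and gene length were also tightened after their values were seen, each toward leaving the explanation open, for the reasons given with each. For neural tissue a stricter bound was likewise set beside the written condition after the value was seen.

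The interaction test called 1 probe set and, at the preset correlation, 5 gene lists, of which none held with an estimated correlation or by fry (adjusted p by fry from 0.117 to 0.866, with an unadjusted p under 0.05 for 3 of them). Probe set 1634590_at, which names no gene, fell on lithium in the wild type (log2 -1.43) and rose in the mutant (1.23), a gap of 2.66. Its signal was high in CS_0 and Shu_50 and low in the other 2 groups. The median over a list's genes of the interaction value was 0.0585 for amino acid metabolism (adjusted p = 0.0222, and 0.624 with an estimated correlation), 0.0714 for synaptic genes (adjusted p = 0.0419, and 0.982) and 0.101 for carbohydrate metabolism (adjusted p = 0.00496, and 0.624). For muscle markers it was 0.109 (adjusted p = 0.00092, and 0.54 with an estimated correlation). For ribosomal protein genes it was 0.0832 (adjusted p = 0.0263, and 0.982), and it turned to -0.0428 under quantile normalization. No single gene of the amino acid list was called by limma in the interaction, and 7 were higher at an unadjusted p under 0.05.

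Other splits of the arrays were counted for each comparison. The 3 against 3 arrays of a main comparison give 10 splits, too few for a share under 0.05. The real split was the 1 with as many calls in each, at 182 for lithium in the wild type (highest other 0), 209 for lithium in the mutant (highest other 58.9% of that), 571 for the untreated genotypes (highest other 1) and 57 for the genotypes on lithium (highest other 0). For the interaction, other splits would carry the lithium effect itself into the count, so the additive effects of genotype and lithium were first taken out. Then 11 of 100 splits gave at least the real count of 1, so chance cannot be excluded, and the highest other gave 41, which points to some structure among the arrays that was not tested. For the average lithium response 1 of 100 splits, the real one, gave as many as 465 (highest other 202). For the average genotype difference it was 1 of 100 again, with 892 (highest other 62). For both averages the share was under 0.05, which covers only arrays placed in groups at random. Since the arrays of a group may share a culture, chance differences between cultures are not excluded.

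Fewer probe sets differed between genotypes on lithium (57) than without it (571). Without CS_0 replicate 3 and Shu_0 replicate 1 the untreated count was 31, and the spread of true differences, corrected for noise, went from an SD of 0.164 (jackknife SE 0.0380) to 0.120, next to 0.116 (SE 0.0105) on lithium. These arrays were picked on a component that separates the genotypes, so leaving them out could remove true differences too, and single outlying arrays stay open as the source. A true effect of lithium on the genotype difference predicts a slope under 1 of the differences on lithium against those without, and the slope was 0.681 (SE 0.208), or 0.957 without the 2 arrays. Both explanations stay open, since the slope lies within 2 SE of 1 and the values without those arrays rest on fewer replicates.

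In the untreated mutant 8 of 31 synaptic genes were called lower, and 4 of 63 oxidative phosphorylation genes and 1 of 69 mitochondrial ribosomal protein genes higher, and none of these lists was called with an estimated correlation (adjusted p = 0.580, 0.597 and 0.580). A bias with gene length may contribute, since the change fell with gene span (Spearman -0.218 untreated and -0.198 on lithium, across genes). The synaptic list's mean nevertheless lay at percentile 1.24 of 10000 lists matched on span. That of oxidative phosphorylation lay at 97.56, just past the range first written for the test. It lies within the range once 2 SE of the random draws (SE 0.156) are allowed, the change made after the value was seen. The mitochondrial ribosomal list lay at 92.17, within the range of matched lists. On lithium the 3 lists lay at 20.01, 98.46 and 89.18 (synaptic, oxidative phosphorylation, mitochondrial ribosomal). Random lists also lack the shared movement of a real list, so the test does not exclude a length bias. A lower share of neural tissue should raise the markers of every other cell type alike, but fat body markers were higher by 0.164 (SE 0.0519) and muscle ones stood at -0.0567 (SE 0.0385), the widest gap, at 0.220 or 3.02 SE. The gap met the condition written against a lower neural share. As the widest of 10 pairs it fell short of a bound adjusted for them, 6.07 SE, which was set after the value was seen. The gap therefore cannot decide. The lists taken as other cell types also included glia and photoreceptors, which a lower neural share could lower as well. Pan-neuronal (-0.144, SE 0.0521) and glial means (-0.0434, SE 0.0219) were lower without overlap of the arrays. Photoreceptor (0.0317, SE 0.0302) and hemocyte means (0.00520, SE 0.0339) overlapped. A lower neural share and a change in the fat body itself both stay open. For RNA integrity, 1 of 3 control genes had 3' to 5' ratios that did not overlap between the genotypes (eIF-4a), which leaves it open, and the mutation itself is an untested biological explanation.

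Probe sets differing between the mutant and the wild type might reflect the stocks rather than the mutation. Among the 50 genes on each side of para lay 5 of 480 called genes and 60 of 8099 others in the untreated comparison. The odds ratio was 1.41 (Fisher's exact p = 0.412). On lithium there were 2 of 46 (odds ratio 6.11, exact p = 0.0473, not past adjustment). Averaged over treatments there were 10 of 744, para itself included, and 55 of 7835 others (odds ratio 1.93, exact p = 0.0714). CanA-14F and Had1 were among the called genes near para in each of these. Tests of genes near para and of genes on the X were repeated with other processing. Under quantile normalization 2 of them gained an exact p under 0.05. With probe sets of unadjusted p under 0.001 taken as called, 1 did. The test near para on lithium lost its exact p under 0.05 in both. Linkage to the mutated locus cannot be told apart from no linkage at these counts, and differences elsewhere in the stocks were not testable. A different share of males and females was tested on the yolk protein genes, whose largest untreated difference was 0.0830 in size. The female-enriched gene fit was higher in the untreated mutant (0.46, adjusted p = 0.0285, or 0.146 without Shu_0 replicate 1), and on lithium the mean of the male-enriched markers was higher (0.386, SE 0.168, without overlap of the arrays) and so was that of the female-enriched ones (0.1802, SE 0.112). Since no probe set is named as a male-specific roX gene, a different share stays open.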

How the results depend on the processing

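Of the alternatives here, those without CS_0 replicate 3 and Shu_0 replicate 1 were chosen only after the data were seen. Of 378 values of called genes, run under 8286 alternatives in all, 6616 stayed past the threshold in the same direction, 1670 lost the call and 0 reversed. The cause was not tested for any change below, except that fewer arrays or probe sets enter where some are left out. Signals near the background limit what is seen, as with List probe set 1626311_at.

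Without the intensity trend the counts were 44 (lithium, wild type), 91 (lithium, mutant), 59 (genotypes untreated), 25 (genotypes on lithium), 0 (interaction), 223 (average lithium) and 329 (average genotype). Without the 2 arrays they were 89 for lithium in the wild type, 31 untreated, of which 31 were among the 571, 295 and 333. Without the filter, lithium in the wild type gave 118 and the interaction 0, with 0 also at the 60th percentile filter. The correlation of the lithium responses was 0.103 and 0.507 under those filters. The 6 arrays alone gave 324 untreated. Array weights gave 133 on lithium and 2 in the interaction, and quantile normalization 2. Of the 38 gene list calls at the preset correlation, 23 were lost and 3 reversed under quantile normalization, 16 were lost without the 2 arrays, 5 with a replicate block, 3 with the mean of all probe sets of a gene, 37 with an estimated correlation and 34 by fry. Under quantile normalization the ribosomal medians were 0.0429 (lithium, wild type), -0.0219 (genotypes on lithium) and -0.0428 (interaction), and the X odds ratio of the average genotype difference was 0.995.

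With a replicate block, the number as a term, the counts were 100 for the genotypes on lithium and 2 for the interaction, and no other count moved by over 1.5 times. Deviations of same-numbered arrays correlated between -0.0649 and 0.0918 (mean 0.0192), and those of other numbers at a mean of -0.00963. Over all probe sets no strong pairing by number was seen, and such weak correlations cannot exclude one. Antimicrobial genes did follow the number. Their list mean was highest in replicate 1 of each group (0.121 in CS_0, 0.661 in Shu_0, 0.0046 in CS_50 and 0.182 in Shu_50). So were the signals of DptB and PGRP-SB1, while AttD and CecB did not follow the number in every group. The replicate numbers are those of the titles, and the description of CS_50 replicate 2 says sample 1, so the numbers of the CS_50 arrays are uncertain in all of these.

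With 1 array left out the counts ranged over 78 to 229, 127 to 238, 129 to 691, 30 to 69, 0 to 1, 312 to 531 and 528 to 1071, in the order above. The correlation ranged over 0.234 to 0.279, and the covariance of the lithium change in the mutant with the genotype difference, beyond shared noise, over -0.00781 to -0.000679.

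Uncalled values changed sign, given as the range without 1 array. For List probe set 1626311_at these were -0.18 to 0.40 and -0.17 to 0.24 for lithium in the wild type and the mutant, -0.37 to 0.21 untreated, -0.21 to 0.00282 on lithium, -0.34 to 0.24 for the interaction, -0.0585 to 0.23 for average lithium and -0.25 to 0.0410 for average genotype. Without the 2 arrays it gave 0.16 untreated and 0.0160 for average genotype, and with array weights 0.0925 untreated. List probe set 1636594_at ranged over -0.15 to 0.0395 untreated and -0.00839 to 0.0871 for average genotype. For GstS1 the ranges were -0.12 to 0.0264 for lithium in the mutant, -0.12 to 0.0237 on lithium, -0.0231 to 0.0533 for average lithium and -0.0258 to 0.0506 for average genotype. The covariance excess of lithium in the wild type ranged over -0.000361 to 0.00647.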

Other observations

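In this part, the set of folate one-carbon and purine synthesis genes was written after the lithium results were seen, and the condition for reading the covariance was tightened after its value was seen. Some genes that differed between the untreated genotypes moved the opposite way on lithium in the mutant. Lower in the mutant and raised there by lithium were 21 probe sets (4.02 given by independent lists). They included hgo (-0.86 against the wild type, 0.44 on lithium), chosen after its values were seen, and Miox, which opens the ring of inositol (-0.64 and 0.72). Without Shu_0 replicate 1, neither call of Miox held (adjusted p = 0.0870 and 0.0641). Higher in the mutant and lowered by lithium were 10 probe sets (1.54 given by independent lists). Among them was the cuticle gene Acp65Aa (0.87 and -0.96), called in both under every alternative. These directions on lithium were not particular to the mutant. Acp65Aa fell in the wild type too (-0.58, adjusted p = 0.0103, or 0.0661 without CS_50 replicate 2). Signals of hgo, not called there, were 251, 316 and 278 in CS_0 and 370, 320 and 318 in CS_50. In the same direction in the mutant were 5 probe sets higher in both (2.87 given by independent lists) and 4 lower in both (2.16). The untreated genotype comparison and lithium in the mutant both use the Shu_0 arrays. A high value there lowers the change on lithium, so independent lists are not the right yardstick here. The covariance of these changes over all probe sets was -0.0239, below all 100 values simulated for unchanged groups that share the arrays (-0.0209 to -0.0175, mean -0.0191), while the correlation, -0.412, was weaker than the -0.543 to -0.490 simulated. The covariance met the condition written for excluding the shared arrays, but the simulation assumes independent probe sets, and the difference of -0.00481 was smaller than its jackknife SE over arrays, 0.00558, so part or all of the opposed movement may come from the shared arrays. With lithium in the wild type, which shares the CS_0 arrays, the covariance was 0.0223, beside 0.0166 to 0.0206 simulated (mean 0.0186). The correlation was 0.397, beside 0.489 to 0.559. There 12 probe sets were higher in both comparisons (2.37 given by independent lists) and 12 lower in both (2.07).

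Lists for known lithium targets showed little among the genes tested, and RNA levels do not measure whether a kinase was inhibited. Of 27 genes listed for the Wnt pathway, which lies downstream of the lithium-inhibited kinase sgg, only 9 were tested. Of these 9, limma called none in either genotype, with 1 lower in the wild type and none in the mutant at an unadjusted p under 0.05. The list was not called (medians 0.00339 and -0.00803, adjusted p = 0.835 and 0.9). Of 21 genes of inositol metabolism 1 rose in the mutant, Miox, and none was called in the wild type by limma (2 were lower at an unadjusted p under 0.05). The list was not called (medians 0.011 and -0.0346, adjusted p = 0.835 and 0.9). Among 28 amino acid transporters List alone was called in each genotype, and the list was not (adjusted p = 0.782 and 0.677). Of 18 genes of oxidative stress defence the thioredoxin reductase Trxr1 rose in the wild type (0.38), and the metallothioneins MtnD, MtnB (0.74) and MtnA (0.29) in the mutant, with the list not called in either (adjusted p = 0.0572 and 0.163). The call of Trxr1 was lost without CS_50 replicate 3 (adjusted p = 0.0928), and that of MtnB without Shu_0 replicate 1 (adjusted p = 0.183). The call of MtnA was lost under 16 of 22 alternatives, 10 of them single arrays left out (adjusted p = 0.128 without Shu_0 replicate 2). Whether the genotypes differ in these responses was tested only by the interaction, which called none of these genes.

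Since Nmdmc, Shmt, pug, Gart and Pfas rose in both genotypes, a hypothesis was that lithium may raise the folate one-carbon and purine synthesis pathway as a whole. The 8 members that had not been seen before the test did not move together, with a mean of 0.0388 and 4 of 8 higher, and the rotation test fry gave them a p of 0.961. Prat2 was the 1 called among them (0.49, average over genotypes). The rotation test that allows both directions gave 0.00965. The 10 members already seen, Paics among them, were all called higher on average over genotypes (mean 0.686). The unseen members are those left once these called genes were set aside. Their test therefore leans toward no change and cannot decide on the pathway as a whole. The rise is shown only for the members called.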
